A study of Homo sapiens with 4 samples.

How the data were processed

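RNA from OUMS-36 fibroblasts was biotin-labelled and hybridised to Affymetrix Human Genome U133 Plus 2.0 arrays, 1 array each for untreated cells and for cells at 0, 1 and 3 h after 30 min at 41 °C. The values used were the signal intensities deposited by the authors, which the submitters' processing notes attribute to MAS5, an algorithm that summarises the probes of a probe set into 1 linear signal after background correction and scales each array as a whole. The version and the target of the scaling are not given in the sources used here. The mean signal of each array after trimming 2% at either end was 500.1, the same on all 4. Detection calls were not used here. The table held 54675 probe sets, of which 62 were array controls, with no missing values and no value at or below 0.

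Gene names came from the platform annotation, and symbols were brought up to date through the gene identifiers of NCBI RefSeq (assembly GRCh38.p14, used for names alone). Outside the array controls, 41091 probe sets named 1 gene, 1801 named several genes and 11721 were not listed. Probe sets with several genes named none here, and some list members have no value for that reason. Genomic positions are not given because the probe sets carry no genome build. Older symbols in the gene lists were matched through RefSeq synonyms.

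The values were used as deposited, without further scaling. Values under the 25th percentile of all values, 10.67, were set to that floor, and log2 was taken. A gene was represented by the probe set with the highest mean over the 4 arrays among those naming it alone. It was counted as expressed where that mean was at or above the 50th percentile of all values, 44.25. A further level, the 75th percentile of 356.01, was used to separate bright from dim genes. This level had been fixed beforehand as another setting of the filter, but its use for choosing and describing genes was decided after seeing the data. A gene was counted as higher or lower where the difference was at least 2-fold, a log2 difference of at least 1 in size. Where 1 of the signals was at the floor, the fold is a bound. For part of the named genes the report also gives the median difference of the gene's other expressed probe sets, among them the bright genes and genes of the naming rule whose others went the opposite way or much less far.

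With 1 array per condition there was no test between conditions. The 5 comparisons were each heat array with the control, 1 h with 0 h, and 3 h with 1 h. The number of arrays limits the precision: the spread of log2 differences between the 0 h and control arrays, as a robust SD, was 0.66 in the dimmest of 20 brightness bins of expressed genes (median signal 49.8) and 0.11 in the brightest (median signal 15308). Gene lists were fixed before the data were examined, and 29 lists were used. For each list with at least 3 expressed members, the median log2 difference was set against 10000 random lists of the same size. Each member was replaced by 1 of the 100 other genes nearest in mean signal. The percentile describes these arrays and is no test of the conditions. Over 87 combinations of list and time, 23 lay outside the central 95% of their random lists. By chance 4.4 would be outside if the members of a list varied as independently of each other as randomly drawn genes, which was not tested. Of these 23, 7 stayed outside in every processing alternative.

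Chance overlap between comparisons that share the control was estimated from 100 sets of 4 simulated unchanged arrays. Noise was drawn from the 0 h minus control differences in the same brightness bin, which treats all of those differences as noise. The sign of each draw was set at random. In these sets between 106 and 173 genes were 2-fold higher, or lower, in a comparison. The counting step was tested on simulated data for the 1 h and control comparison, with randomly chosen genes changed by known amounts. Among 12088 expressed genes it called 96.0% of genes raised by 1.5 on the log2 scale, 98.0% of those lowered by 1.5 and 100.0% of those changed by 3.0, and 1.47% of unchanged genes. Among 7894 bright genes it called 0 of 7745 unchanged genes. The noise in that test was normally distributed, so outlying probe sets were not represented. Its size came from the 0 h minus control differences. Among bright genes the robust SD of differences from the control was 0.139 at 0 h but 0.268 at 1 h. The 0 calls therefore hold for the smaller spread and give no error rate for the 1 h array.

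The rule for naming genes was fixed before the data were examined. For each comparison with the control it took the 10 largest rises and 10 largest falls among expressed genes at least 2-fold different, with both signals above the floor and all expressed probe sets differing in the same direction. It added the 3 largest bounds in each direction and up to 4 members of each list with the largest difference at any time. For successive times it took 5 rises and 5 falls. Because this rule chose mostly dim genes, the same rule was also applied to bright genes. Further bright genes past 2-fold at 0, 1 or 3 h are named with their values.

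The settings fixed beforehand for comparison were median centring, quantile normalization, no floor, a floor at the 50th percentile, no filter, a filter at the 75th percentile, the mean of all expressed probe sets of a gene, leaving out probe sets whose names end in _x_at or _s_at (which can bind several transcripts), and thresholds of 1.5-fold and 3-fold. Added after seeing the data were a requirement that other probe sets agree by at least 0.5 on the log2 scale, a requirement of 2-fold from both the control and the 0 h array, and combinations of these or of quantile normalization with the filter at the 75th percentile. Analyses were run in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.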

Results

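The series followed gene expression in OUMS-36 cells, a line of normal human fibroblasts, after a mild heat exposure. Cells were kept at 41 °C for 30 min and then returned to 37 °C for 0, 1 or 3 h, and untreated cells were the control. Transcripts were measured on Affymetrix Human Genome U133 Plus 2.0 arrays, on which each transcript is read by 1 or more probe sets of short oligonucleotides. Each of the 4 conditions had 1 array, so no difference below was tested against replicate cultures, and none has an error or a p-value. The 1 untreated array served all 3 times, and its label gives no time of harvest. A change with time in culture therefore cannot be told apart from an effect of heat. All values are MAS5 signals in arbitrary units, and differences are log2 of the heat array over the control array unless stated otherwise. Of 19775 named genes, 12109 had a mean signal of at least 44.25 and are called expressed, and 7880 of these had a mean of at least 356.01 and are called bright. The median signal over all probe sets was 43.3 on the control array and 45.1, 44.8 and 44.1 on the 0 h, 1 h and 3 h arrays.

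The first comparison asked what had changed at the end of the heat exposure, before any return to 37 °C. Very few well-measured genes differed from the control at 0 h. Among bright genes, 1 was at least 2-fold higher and 2 were at least 2-fold lower. These were ASB6 (log2 difference 1.03), and ZBED1 (-1.15) and ST3GAL2 (-1.07), and the other probe sets of the same genes differed by medians of -0.20, -0.39 and 0.15. They are named here because the count is small, after their values were seen. The inducible chaperone HSPA6 was 0.39 higher on the log2 scale, and the HSP40 chaperone DNAJB1 was 0.15 higher. The 21 expressed genes of HSP90 and its co-chaperones had a median difference of 0.13, against 0.03 in random gene lists matched on signal, which put the list at percentile 99.72. That list lay at percentile 95.32 in the least favourable of the processing alternatives. No expressed member of the 5 chaperone lists was 2-fold higher or lower at 0 h. The immediate early genes, transcription factors and regulators that cells switch on first after a stimulus, had a median of 0.01 over 29 expressed members. The lists of ER stress genes (median 0.09, percentile 97.48) and metallothioneins (median 0.21, percentile 97.07) lay just inside the central 95% of matched random lists.

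Over all expressed genes the 2-fold counts at 0 h were larger, at 167 higher and 109 lower, but 166 of the higher and 107 of the lower genes were dim. The 10 largest rises with both arrays above the floor were those of ZNF414, KDM8, DTWD2, TSPAN32, FMNL1, TBC1D27P, SLCO4A1, PRB1, ERN2 and GPRIN1, with log2 differences of 2.29 to 3.74. The 10 largest falls were those of PIANP, MDGA1, ABHD8, IKBKB-DT, PNMA3, DGCR5, ZNF658, CHDH, NOVA2 and C16orf86, with log2 differences of up to 3.05 in size. In all 20 genes the lower of the 2 signals was 50.4 or less, close to background, and the size of a difference at that level is poorly determined. Among genes with a control signal at the floor of 10.67, the largest rises were at least 10.3-fold for IKZF1, 8.74-fold for WNK2 and 8.42-fold for CD34. The other probe sets of ERN2, NOVA2 and WNK2 were at 0.61, -0.40 and -0.35. ADAMTS10, GAS7 and RND2 were at the floor on the 0 h array and at least 9.47-fold, 7.52-fold and 6.63-fold lower.

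After 1 h at 37 °C, genes of the ER stress and unfolded protein response were higher as a group. The list holds genes that handle misfolded proteins in the secretory pathway and also regulators of the stress response, such as DDIT3. Of 27 expressed members, 23 lay above the control and 5 were at least 2-fold higher. DDIT3, also called CHOP and a transcription factor of this response, went from a signal of 505.4 to 2377, a log2 difference of 2.23. CHAC1, an enzyme that degrades glutathione, was 1.66 higher and HERPUD1, a part of the machinery for ER-associated protein degradation, was 1.47 higher. The ER co-chaperones SDF2L1 and DNAJB11 were 1.15 and 1.01 higher. The list median was 0.39 against 0.10 for matched random lists, at percentile 100 as deposited and in each of the 9 processing alternatives. HSP90B1, the ER member of the HSP90 family, went the other way at -1.15, and its other probe set was at -1.09.

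Most expressed chaperones outside the ER stress list were also higher at 1 h, few of them by 2-fold. In the HSP70 and HSP110 family, 3 of 9 expressed members were at least 2-fold higher. These were HSPA1L (1.30), HSPA6 (1.24, from 606.2 to 1432) and HSPA4L (1.08), followed by HSPH1 at 0.61, whose other probe sets were at -0.09. HSPA1L and HSPA4L were dim. HSPA6 and HSPA1L are near-identical in sequence to other HSP70 genes, so part of their signal could belong to those, and the probe sets of HSPA1A, HSPA1B and HSPA8 each list several genes, so these main HSP70 genes are missing from the count and were not analysed here. Among 19 expressed HSP40 genes, 13 lay above the control. DNAJB1 was 0.68 higher and DNAJB4 0.53 higher, and DNAJA4, at 1.26, was the only one past 2-fold. DNAJC16 went the other way at -0.61, with its other probe set at -0.06. DNAJA4 was dim, and its other probe sets had a median of -1.01. The co-chaperones FKBP4 (0.60), BAG3 (0.55) and CACYBP (0.51), the small heat shock proteins CRYAB (0.53) and HSPB8 (0.52), and the chaperonins HSPE1 (0.47) and CCT5 (0.40) were higher without reaching 2-fold. The other probe set of HSPB8 went the opposite way, at -0.30. On the same array the housekeeping gene GAPDH was at 0.46, and the brightest of 20 bins of expressed genes had a median of 0.24. Values like those of HSPE1 and CCT5 were thus not particular to chaperones. The medians were 0.23 for HSP40 and 0.38 for small heat shock proteins, against 0.06 and 0.09 in matched random lists. Those of HSP90 with co-chaperones and of chaperonins were 0.26 and 0.30, against 0.10 and 0.16. Each of these lists lay between percentiles 98.66 and 99.47 of matched random lists, and the HSP70 list lay at 96.62. The small heat shock protein list fell to percentile 86.18 and the HSP40 list to 84.28 in the least favourable alternative. The HSP90 list fell to percentile 23.00 and the chaperonin list to 97.19 in theirs. The 8 expressed heat shock factors and their regulators had a median of 0.19, at percentile 72.94, and none was past 2-fold.

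Several transcriptional regulators and signalling genes were at least 2-fold higher at 1 h. In all, 21 bright genes were at least 2-fold higher, and taking the 0 h array as a second baseline left 13. EDN1, the precursor of the vasoconstrictor endothelin, had a log2 difference of 2.20, with other probe sets at 0.69. The transcriptional repressor and clock gene BHLHE40 was 2.00 higher and the repressor HES1, a Notch target, was 1.28 higher. DDIT4 (REDD1), an inhibitor of mTORC1 signalling, was 1.91 higher. The transcription factors DLX2 (1.53), SNAI2 (1.32) and CSRNP1 (1.27), the adaptor protein NEDD9 (1.41), the haem-degrading enzyme HMOX1 (1.24) and the immediate early gene IER3 (1.09) were also past 2-fold. These bright genes were taken up after the values had been seen, because the rule fixed beforehand ranked mostly dim genes. The immediate early list had a median of 0.24 at percentile 99.97, with 2 members higher and 3 lower by at least 2-fold. The lower ones were FOS (-1.31), NR4A2 (-1.31) and ZFP36L1 (-1.003). This list was inside the central 95% in 2 of 9 processing alternatives, down to percentile 85.53. The list of serum response, TGF-beta and YAP targets had a median of 0.30 at percentile 99.57, with SMAD7 at 0.82, SKIL at 0.62 and ID1 at 0.58, and none past 2-fold.

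**Figure D1:**
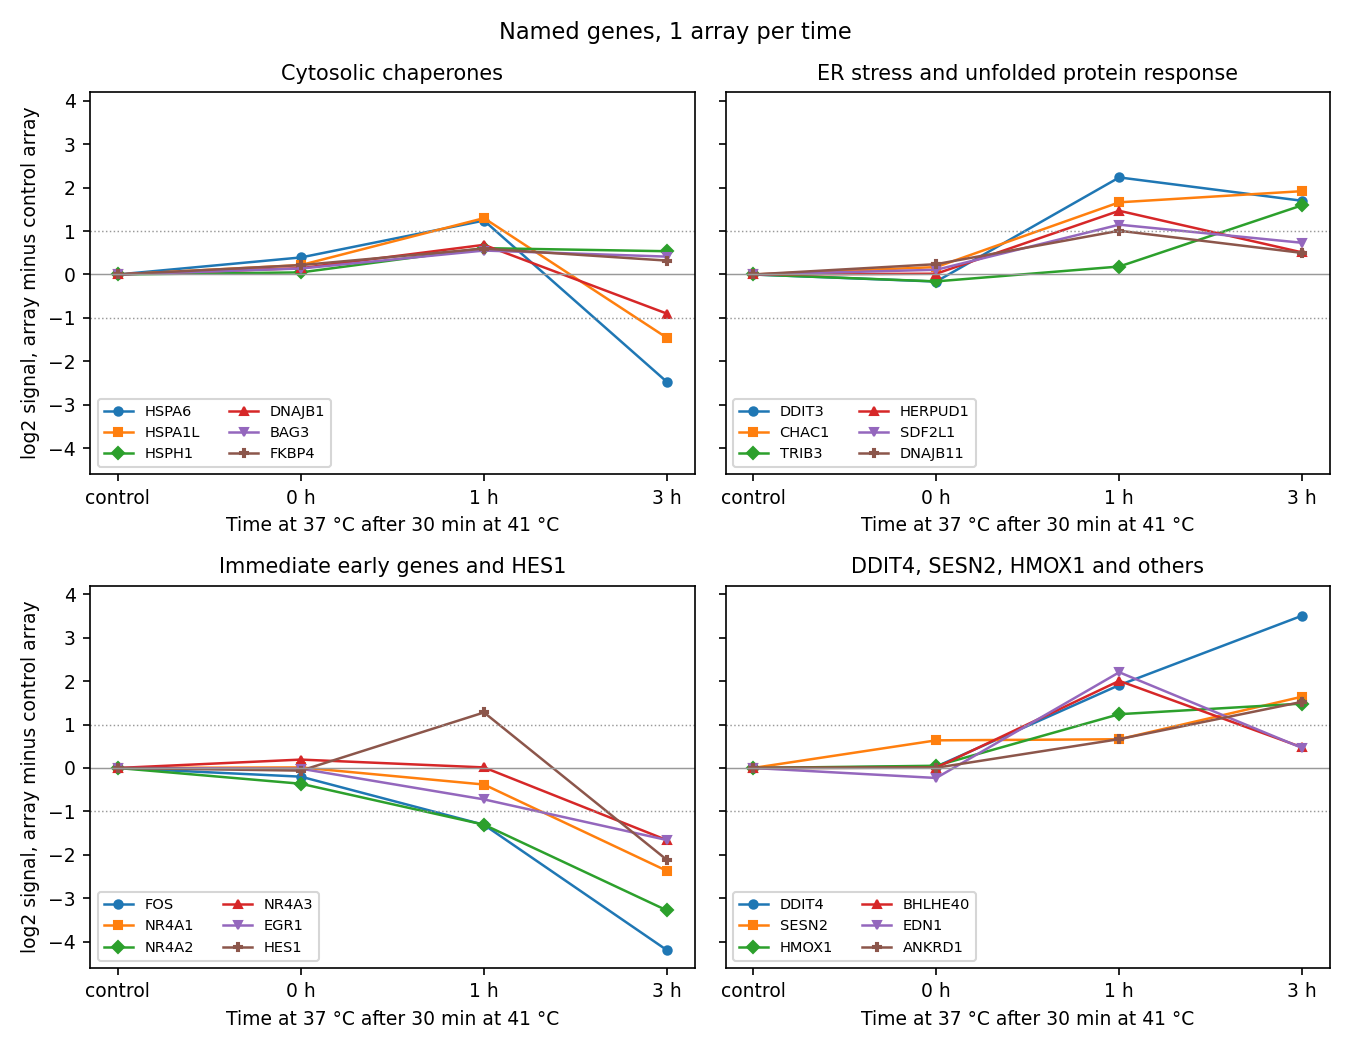
Log2 signal of named genes on each heat array minus the control array (vertical axis) at 0, 1 and 3 h after 30 min at 41 °C (horizontal axis, with the control at 0). Each point is 1 array, lines join points of the same gene, and dotted lines mark 2-fold. HSPA6 and HES1 lie above the control at 1 h and below it at 3 h, whereas DDIT4 is highest at 3 h, at 3.51. The FOS value at 3 h, -4.20, is a bound because its signal was at the floor.

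Lower signals at 1 h were more numerous than higher ones among bright genes, at 73 against 21. The largest falls under the naming rule among bright genes were those of the kinase CDC42BPA (-2.97), ANKRD12 (-2.62), SLFN5 (-2.39), EDEM3 (-2.39), SECISBP2 (-2.17), ANKRD17 (-2.16), NKTR (-2.05), MPHOSPH8 (-1.99), SRGAP1 (-1.91) and MBP (-1.86). In the same order the medians of the other probe sets were -0.12, -0.67, -0.27, -1.16, -0.39, -0.15, -0.97, -0.10, -0.90 and -0.81. The nuclear long non-coding RNA MALAT1 was at -2.78, and its other probe sets were at -0.43. Among the p53 target genes, 3 of 22 expressed members were at least 2-fold lower, TP53INP1 (-2.06), ZMAT3 (-1.78) and SESN1 (-1.29), and the list median was -0.15 at percentile 0.40. Its call was lost in 2 of 9 alternatives. TP53INP1 and SESN1 were dim, with 1 expressed probe set each, and the other probe sets of ZMAT3 were at -0.16. Only 3 of the 73 genes were still 2-fold lower at 3 h, MBP, PDE4D and SHC4, and the other probe set of SHC4 was at -0.45 at 1 h. Of the 73 genes, 70 had further expressed probe sets, and in 24 of these the others were lower too, by a median of at least 0.5. HSP90B1, EDEM3, GOLGA2 and TXNIP, a thioredoxin inhibitor at -1.11, were among those 24. On the same array, the 3′ probe set for 18S ribosomal RNA was 1632 against 4200 in the control, and the 5′ probe set 24577 against 25082. Among bright probe sets that were not the brightest of their gene, 353 of 4422 (7.98%) were at least 2-fold lower at 1 h, against 0.93% of the brightest probe sets. At 3 h these shares were 0.36% and 0.38%.

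**Figure D2:**
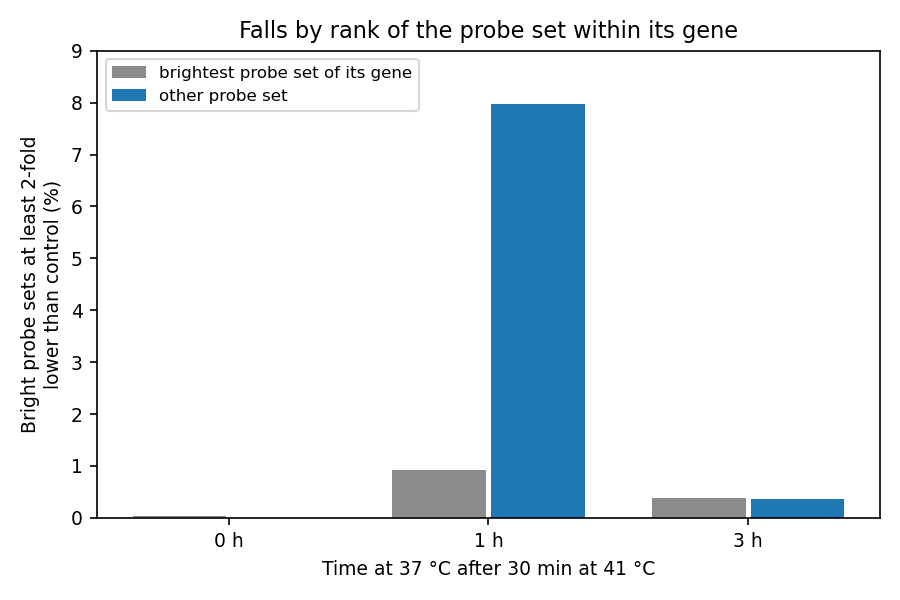
Share of bright probe sets at least 2-fold lower than the control (vertical axis, percent) at 0, 1 and 3 h after heat (horizontal axis), for the brightest probe set of each gene (grey, 7880 probe sets) and for the other probe sets (blue, 4422). The share is 7.98% for the other probe sets on the 1 h array and at most 0.93% in every other bar.

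Over all expressed genes, 205 were at least 2-fold higher and 230 at least 2-fold lower at 1 h, of which 184 and 157 were dim. Median centring turned this split, to 235 higher and 209 lower, and quantile normalization gave 215 and 211. The 10 largest rises under the rule fixed beforehand were those of TSPAN32, DTWD2, FAXDC2, KDM8, FMNL1, MISP, MYO15B, FBN3, TMEM239 and SLCO4A1, all dim, with control signals between 10.7 and 46.1, and the other probe set of FAXDC2 was at 0.13. Among the 10 largest falls, CDC42BPA, ANKRD12, SLFN5 and EDEM3 were bright and the other 6 were FAM111B, AGAP4, RASEF, ANKRD36B, ESR1 and LOC100128653. FAM111B had a log2 difference of -3.86 with its other probe set at -3.10, and RASEF -2.59 with -2.18. At the floor, ZNF143-AS1, THORLNC and PCDHAC1 were at least 12.9-fold, 9.51-fold and 9.32-fold higher than the control. CRY2, a repressor of the circadian clock, PKD1P1 and PLB1 were at least 11.7-fold, 10.6-fold and 8.19-fold lower.

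After 3 h at 37 °C, DDIT4 was the bright gene farthest above the control, with a signal of 2617 against 230.2 (log2 difference 3.51). The ER stress genes stayed higher as a group, with a median of 0.42 over 27 expressed members, 24 of them above the control, at percentile 100 as deposited and in each alternative. The members past 2-fold were CHAC1 (1.92), DDIT3 (1.70) and TRIB3 (1.59), a pseudokinase induced by ATF4 and DDIT3. HERPUD1, SDF2L1 and DNAJB11, past 2-fold at 1 h, were at 0.51, 0.73 and 0.50. SESN2, a stress-induced inhibitor of mTORC1, was 1.64 higher with its other probe set at 1.00. Genes of the NRF2 and oxidative stress response had a median of 0.42, with 15 of 16 expressed members above the control, at percentile 100. In that list HMOX1 was 1.48 higher, MAFG 0.57 and TXNRD1, the cytosolic thioredoxin reductase, 0.48. The list had been at percentile 15.34 at 1 h, when HMOX1 was already past 2-fold. The list of metallothioneins, small metal-binding proteins, and their regulators had a median of 0.41 at percentile 100. Among its members MT1M, a dim gene, was at 1.26 (from 38.99 to 93.14), MT1G at 0.43 and the zinc exporter SLC30A1 at 0.58. Metallothionein genes are near-identical copies, so their separate values are uncertain, and the percentile counts each as a separate gene. The housekeeping genes had a median of 0.16 on the same array.

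Other bright genes at least 2-fold higher at 3 h were KCNE4 (1.30), ENC1 (1.29), KRTAP1-5 (1.28), LURAP1L (1.04) and CLIP3 (1.00), as well as BICD1 (1.18), whose other probe sets were at -0.58. That of ENC1 was at 0.33. The cardiac and YAP-regulated gene ANKRD1, which was dim, was 1.52 higher, from 149.5 to 429.6. In total 12 bright genes were at least 2-fold higher. CHAC1, DDIT3, DDIT4 and HMOX1 were the 4 bright genes at least 2-fold higher at both 1 h and 3 h. Among chaperones, HSPH1 (0.54) and BAG3 (0.41) remained above the control, HSPB8 was at 0.50 with its other probe set at -1.58, and the HSP90 list had a median of 0.20 at percentile 99.84. That list was inside the central 95% in 3 of 9 alternatives, down to percentile 53.78. The proteasome and ubiquitin list had a median of 0.17 at percentile 98.88, and 94.84 in the least favourable alternative.

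Lower signals at 3 h included immediate early genes and a subset of chaperones. FOS was at the floor, at least 18.3-fold lower than the control. The nuclear receptors NR4A2, NR4A1 and NR4A3 had log2 differences of -3.28, -2.37 and -1.66, and EGR1, a zinc-finger transcription factor, -1.66, from 10402 to 3293. The other probe sets of NR4A2 and EGR1 were at -2.78 and -1.54, but that of NR4A1 was at -0.29. These were the 5 members of the immediate early list past 2-fold. The list median was -0.11 at percentile 0.43, and the call was lost in 4 of 9 alternatives. Among bright genes after quantile normalization the median lay 0.01 above matched lists. HSPA6 was at -2.47, HSPA1L at -1.46 and DNAJB1 at -0.90, all below the 1 untreated array after being above it at 1 h. Of the 9 expressed members of the HSP70 and HSP110 list, 5 lay above the control and 2 were at least 2-fold lower. The list median was 0.24, at percentile 99.77, and at 16.81 with no filter on dim genes. HES1 was at -2.12 with its other probe set at -1.93.

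Among the 30 bright genes at least 2-fold lower at 3 h were MN1 (-1.58), MBP (-1.53), the phosphodiesterases PDE7B (-1.48) and PDE4D (-1.14), SHC4 (-1.31), the phosphatase regulator PPP1R10 (-1.25), TRAF5 (-1.21), IER5L (-1.19), the tendon transcription factor MKX (-1.19), CXCL6 (-1.04) and the lipid phosphatase PLPP3 (-1.03). Of 20 with further expressed probe sets, 14 had others lower by a median of at least 0.5. Those of MBP were at -0.71 and that of IER5L at -0.55. RSRP1 (-1.67) and PCF11 (-1.47), both of which act in pre-mRNA processing, had other probe sets at 0.34 and 1.16. Extracellular matrix genes were low relative to their brightness. Their median was -0.04 over 30 expressed members, against 0.14 for matched random lists, at percentile 0.00, and none was past 2-fold. At 1 h the list lay at percentile 0.21, a call lost without probe sets able to bind several transcripts (percentile 9.04). COL12A1 was at -0.51 at 3 h and MMP2 at -0.49. Genes of G2 and mitosis had a median of -0.05, against 0.05 for matched lists, at percentile 1.81. Within that list CCNF was at -0.44 and TTK at -0.37, whereas 10 of 29 members lay above the control. Among those were KIF20A at 0.265 and BIRC5 at 0.274, with the other probe sets of BIRC5 at -0.054.

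**Figure D3:**
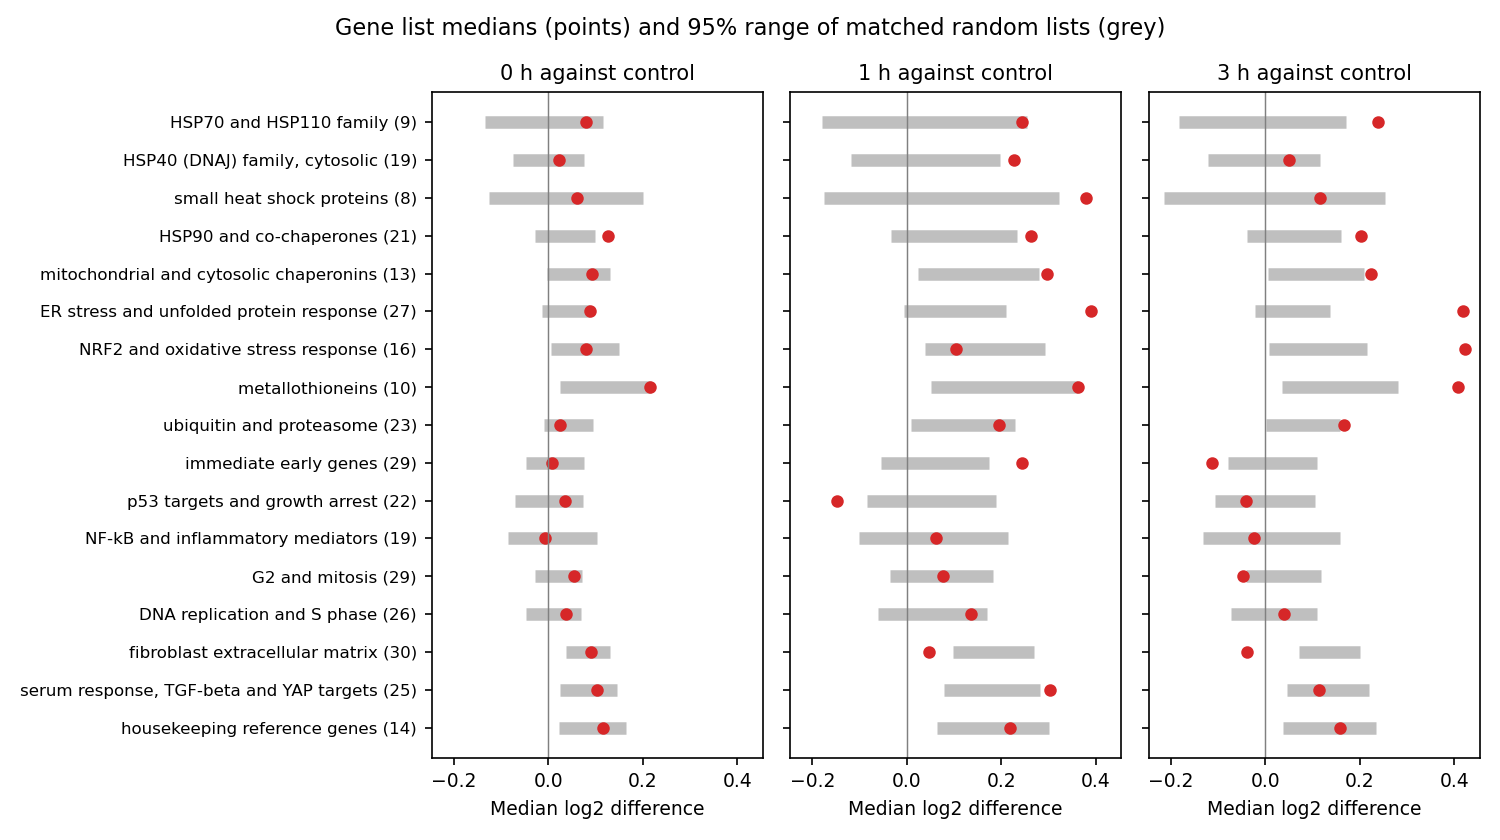
Median log2 difference of the expressed members of 17 gene lists (red points, number of members in brackets) on the 0 h, 1 h and 3 h arrays against the control. Grey bars span the central 95% of the medians of 10000 random lists matched on mean signal. The ER stress list lies to the right of its bar at 1 h and 3 h (0.39 and 0.42), and the extracellular matrix list to the left of it at both times (0.05 and -0.04).

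Over all expressed genes, 198 were at least 2-fold higher and 232 at least 2-fold lower at 3 h, of which 186 and 202 were dim. Median centring of the arrays turned this split, to 240 higher and 183 lower, and quantile normalization gave 208 and 204. Apart from DDIT4, the 10 largest rises under the rule fixed beforehand were in dim genes, ZNF414, SPTB, PRB1, DTWD2, KDM8, TSPAN32, TINAGL1, PROKR2 and FCGR2C, whose other probe set was at 0.47. The 10 largest falls were those of NR4A2, CYTOR, VILL, SPRY4-IT1, KRT9, GATD1-DT, XIRP1, TSGA10IP, HSPA6 and LINC00944, all dim except HSPA6. At the floor, WNK2, PDE6B and THORLNC were at least 8.77-fold, 7.91-fold and 7.15-fold higher, with the other probe set of WNK2 at 0.20, and STK33 and LRFN5 at least 9.35-fold and 7.34-fold lower.

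Other programmes showed smaller or mixed differences. In the NF-kB and inflammatory list the medians were -0.01, 0.06 and -0.02 at 0, 1 and 3 h. RELB (1.21) was higher and CXCL3 (-1.07) lower by at least 2-fold at 1 h. At 3 h CXCL2 (1.05) was higher and CXCL6 lower by at least 2-fold. RELB, CXCL3 and CXCL2 were dim, with 1 expressed probe set each, and CXCL6 was bright. The type I interferon list had medians of 0.10, 0.18 and 0.02 and no member past 2-fold. DNA replication genes, cholesterol synthesis genes, and SR proteins with CLK kinases and cold-inducible RNA-binding proteins stayed inside the central 95% of matched lists at all 3 times, with no member past 2-fold. CLK1, a kinase of splicing factors, was at -0.93 at 3 h. Glycolysis and hypoxia genes lay at percentiles 97.41, 92.80 and 46.90, and DDIT4 was their only member past 2-fold. The circadian clock list had medians of -0.12, -0.19 and -0.22, at percentiles 3.00, 1.96 and 2.12, with CRY2 and RORA lower and BHLHE40 higher by at least 2-fold at 1 h. CRY2 and RORA were dim. The call of the clock list was lost in 6 of 9 alternatives at 1 h and in 5 at 3 h. Apoptosis regulators had medians of -0.03, 0.10 and -0.07. The death receptor TNFRSF10A, a dim gene, was at -1.22 at 1 h, with its other probe sets at -0.57.

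The cells expressed fibroblast markers on every array. All 16 were bright, with a median signal of 6067 in the control and 6230, 4951 and 5583 at 0, 1 and 3 h, and none was 2-fold different at any time. Markers of other cell types were mostly near background. Of 13 measured epithelial markers only KRT18 and DSP were bright, of 9 melanocyte and neural markers only MITF, and of 12 endothelial and 11 blood markers none. Housekeeping reference genes had medians of 0.12, 0.22 and 0.16 at 0, 1 and 3 h, with GAPDH at 0.31, 0.46 and 0.36. Matched random lists had similar medians of 0.10, 0.19 and 0.15, and the spiked hybridisation controls, which contain no cellular RNA, had medians of 0.18, 0.29 and 0.23. The poly(A) spikes, which are not cellular either, had medians of -0.03, 0.17 and -0.04. The 3′ to 5′ signal ratio of the ACTB control probe sets was 1.53 on the control array and 1.39, 1.35 and 1.71 on the heat arrays, and that of GAPDH lay between 0.944 and 0.977.

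Successive times were also compared directly. From 0 h to 1 h, 197 genes were at least 2-fold higher and 245 lower, among which 16 and 69 were bright. The 5 largest rises under the naming rule, PIANP, MDGA1, ABHD8, UBXN10 and PNMA3, were dim genes with a low 0 h signal, and the largest falls were those of FAM111B, IKZF1, ESR1, MEFV and ANKRD12 (-2.65, others -0.73). From 1 h to 3 h, 211 were higher and 246 lower, among which 59 and 17 were bright, and median centring gave 231 and 222. HSPA6 had the largest fall, at -3.72, followed by SPRY4-IT1 (-3.64), HES1 (-3.40), CYTOR (-3.15) and XIRP1 (-2.82). The largest rises were those of CYP2D6, GPR3, FAM111B, TCL1A and FRMD6-AS1.

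By time of the largest difference from the control, 97 genes were highest and 88 lowest at 0 h, 130 and 213 at 1 h, and 114 and 211 at 3 h. Among bright genes these numbers were 1 and 1, 16 and 73, and 11 and 26. The lists of genes past 2-fold shared 89 higher genes between 0 h and 1 h, 90 between 0 h and 3 h, and 100 between 1 h and 3 h. Independent lists of these sizes would share 2.8, 2.7 and 3.4. All comparisons used the same control array, and simulated unchanged arrays against 1 control shared medians of 48.0, 49.0 and 48.0. For lower genes the shared numbers were 9, 13 and 31, against 2.1, 2.1 and 4.4 for independent lists and simulated medians of 48.0, 49.0 and 48.0. At all 3 times 63 genes were higher and 1 was lower, against simulated medians of 32.0 (range 23 to 46) and 32.0 (17 to 52). Part of any excess may thus come from the shared control. Across all expressed genes, which are not independent replicates, the log2 differences at 1 h and 3 h correlated with Pearson's r = 0.49 and Spearman's rho = 0.52. Unchanged arrays gave a simulated r of 0.50. Equal noise against 1 shared control gives about that r by construction, so this r neither shows nor excludes a shared change. The covariance of the 1 h and 3 h differences was 0.0939, against 0.0580 in the simulation. The corresponding values were r = 0.43 (simulated 0.50), rho = 0.44 and a covariance of 0.0658 against 0.0581 for 0 h and 1 h, and r = 0.43 (simulated 0.50), rho = 0.41 and 0.0641 against 0.0583 for 0 h and 3 h. Among bright genes r was 0.56 for 1 h and 3 h, 0.45 for 0 h and 1 h, and 0.44 for 0 h and 3 h (simulated 0.50). In the same order the covariances were 0.0479, 0.0234 and 0.0191, against 0.0124, 0.0123 and 0.0123 in the simulation.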

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

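The genes HES1, HSPA1L and HSPA6 lay at least 2-fold above the control at 1 h and at least 2-fold below it at 3 h. HSPA1L was dim, and the others were bright. The log2 difference at 1 h minus that at 3 h was 3.396 for HES1, 2.757 for HSPA1L and 3.715 for HSPA6. These differences between times were not tested, since each time had 1 array. Among 1384 bright probe sets without a single gene name, which the comparisons above leave out, 0 were at least 2-fold higher than the control at 0 h, 10 at 1 h and 3 at 3 h, and 0, 32 and 2 were at least 2-fold lower.

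All tests of the lower signals at 1 h among bright genes were chosen after seeing that result. Loss of signal from single probe sets fits, since only 34.3% of the genes with other expressed probe sets had others lower by 0.5 or more. Different priming inside transcripts during labelling of the 1 h RNA cannot be told apart, because the 3′ and middle 18S ribosomal RNA probe sets were lower (-1.364 and -0.719) but the 5′ one was at 24577 against 25082. Nor can shorter labelled RNA, because the 5′ to 3′ log2 ratio of the poly(A) spikes was lower by a median of 0.277 (-0.277) but those of ACTB and GAPDH were higher by 0.173 and 0.045. Loss from single probe sets may not hold for the 24 genes whose other probe sets were also lower, and a biological explanation stays open, untested.

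The test of the 63 genes at least 2-fold higher on all 3 heat arrays was chosen after seeing that result. Low readings of dim probe sets on the 1 control array cannot be told apart from other explanations, because the test was void. All of these genes (100%) were dim, but they are a subset of the genes higher at 0 h, so their choice alone fixed that share at 98.4% or more. Unchanged arrays sharing 1 control gave a median of 32.0 such genes (range 23 to 46), and 32.0 (17 to 52) lower at all 3 times where 1 was observed. The simulated noise took either sign with equal chance, so the simulation could not give such a split. It therefore does not decide whether the control array read low. No biological explanation was tested, and one stays open.

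The tests of the higher signals of chaperone genes and other bright transcripts at 1 h, and the pooling of 70 expressed chaperone genes, were chosen after seeing that result. A difference in scaling as a cause for bright transcripts in general cannot be told apart, because the spiked hybridisation controls were higher by a median of 0.290 and the poly(A) spikes by 0.166, but bright genes as a whole by 0.050 and the brightest of 20 bins by 0.238. The chaperone genes were also set against genes of like signal. Their median of 0.276 lay at percentile 100 of random lists matched on signal, against a random median of 0.093. That pool was built after its lists had been seen to be high, so the percentile cannot exclude scaling as the whole cause. Heat treatment may account for the difference from matched lists, but with 1 array per condition a difference between cultures could too. That was not tested.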

How the results depend on the processing

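No paired analysis was possible because each condition had 1 array and the labels carry no replicate numbers. Dim genes limit the counts: signals near background vary most, and the filter on signal moved the counts more than any normalization. Median centring moved no count by over 1.5 times, and neither did leaving out the floor. Of the comparisons of counts, 76 stayed within 1.5 times and 90 did not. Of the list medians 732 were the same, 12 moved and 3 reversed, and of the values of named genes 3315 were the same, 314 moved and 3 reversed. Some of the moved list medians also changed sign. Where a value below differs, the cause was not tested, except that fold thresholds and filters change counts by construction.

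Counts are given as higher and lower genes at 0 h, 1 h and 3 h against the control, 1 h against 0 h, and 3 h against 1 h. At 1.5-fold they were 428 and 342, 680 and 689, 577 and 814, 613 and 653, 629 and 745. At 3-fold they were 44 and 34, 58 and 74, 65 and 70, 56 and 75, 69 and 86. With no filter they were 1240 and 791, 1356 and 918, 1268 and 990, 1212 and 1193, 1143 and 1336. With the filter at the 75th percentile they were 1 and 2, 21 and 73, 12 and 30, 16 and 69, 59 and 17. With that filter and quantile normalization, chosen after seeing the data, they were 1 and 2, 24 and 65, 15 and 21, 18 and 63, 58 and 17. With that filter and agreement between probe sets, also chosen afterwards, they were 0 and 0, 19 and 27, 10 and 24, 15 and 19, 21 and 8. With the floor at the 50th percentile they were 76 and 33 at 0 h, 117 higher at 1 h, 97 and 127 at 3 h, 111 higher for 1 h against 0 h, and 135 and 134 for 3 h against 1 h. Requiring 2-fold from both the control and the 0 h array, a choice made after seeing the data, left 50 higher at 1 h, and 50 higher and 151 lower at 3 h. With the filter at the 75th percentile as well it left 13 and 62 at 1 h, and 10 and 18 at 3 h.

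With the filter at the 75th percentile, higher genes shared by 0 h and 1 h, 0 h and 3 h, 1 h and 3 h, and all 3 times numbered 0, 0, 4 and 0, and lower genes 1, 1, 3 and 0. Quantile normalization left 0 genes lower at all 3 times. With the same filter the largest difference was at 0 h, 1 h and 3 h in 1, 16 and 11 higher genes and in 1, 73 and 26 lower genes.

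List medians are given minus those of matched random lists. Those that reversed were HSP70 and HSP110 at 3 h with no filter (-0.086), HSP90 and co-chaperones at 1 h without _x_at and _s_at probe sets (-0.072), and immediate early genes at 3 h with the filter at the 75th percentile and quantile normalization (0.011). Without _x_at and _s_at probe sets, those that moved were small heat shock proteins at 3 h (-0.166), HSP90 at 3 h (0.009), metallothioneins at 0, 1 and 3 h (0.265, 0.303 and 0.746), serum response at 3 h (0.073), SR proteins at 0 h (-0.020) and apoptosis regulators at 3 h (0.088). With the mean of all probe sets they were ER stress at 3 h (0.263), G2 and mitosis at 1 h (-0.145) and SR proteins at 0 h (-0.097). With the filter at the 75th percentile it was NF-kB at 1 h (-0.178). Of these moved medians, some from lists inside the central 95% also changed sign. As deposited, small heat shock proteins at 3 h were at 0.074 and SR proteins at 0 h at 0.049. Serum response and apoptosis regulators at 3 h were at -0.031 and -0.053. Genes that reversed were DNAJA4 at 1 h (-0.252) and BICD1 at 3 h (-0.025) with the mean of all probe sets, and YEATS2 at 3 h (0.75) without _x_at and _s_at probe sets.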

Other observations

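A few bright genes outside the fixed lists had probe sets that moved together. At 3 h the phosphodiesterase PDE7B was at -1.48 with others at -1.29, PLPP3 at -1.03 with others at -1.13, and CENPI, a centromere protein, at -1.05 with others at -0.95. GOLGA2, a Golgi matrix protein, was at -1.59 at 1 h with others at -1.37. TXNIP was at -1.11 at 1 h with others at -0.89, and at 0.45 at 3 h.

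All 4 poly(A) spikes had their lowest 5′ to 3′ ratio on the 1 h array. The middle probe set for 18S ribosomal RNA had signals of 12135, 14085, 7373 and 15405 on the control, 0 h, 1 h and 3 h arrays, and the 5′ probe set 25082, 28006, 24577 and 30974. Array correlations with the control were 0.986, 0.969 and 0.979 at 0, 1 and 3 h.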
